A study of Mus musculus with 12 samples.

How the data were processed

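RNA from 12 samples of mouse splenic CD4+ T cells was measured on 12 Affymetrix Mouse Gene 1.0 ST arrays, which carry probes along whole transcripts and give 1 value per probe set. Per the labels, the cells came from spleens of male C57BL/6 mice aged 6 weeks and were enriched by removing other cells with antibodies, a step that can leave some of them behind. They were activated for 48 h with beads that engage CD3 and CD28. Afterwards 5 samples received IL-12 at 100 U/ml for 2 h, 4 received it for 8 h, 2 were kept without it for 2 h, and 1 is labelled as baseline with no culture time.

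The deposited table holds intensity on a linear scale for 24922 probe sets, and the submitters' processing notes name RMA and Affymetrix Power Tools, with no version. RMA corrects background, equalises the distributions of the arrays and summarises the probes of each probe set. The probe annotation and genome build behind the values are not given in the sources used here. Median intensity lay between 160.6 and 167.3 on all 12 arrays, the lowest value on any array was 7.52 and the highest 21170. All 12 value columns matched 1 sample title each, and 0 columns belonged to other samples.

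Values were log2-transformed and not normalized again. GEO's platform annotation gave 1 gene symbol for 21425 probe sets, several for 1399 and no entry for 2098. Gene identifiers of 21347 of the named probe sets matched the current gene table, 78 did not, and 0 symbols needed an update. Probe sets without exactly 1 symbol were left out of the gene tests. Where a gene had more than 1 probe set, as 921 genes did, the probe set with the highest mean over all arrays stood for it, which left 19752 genes. No gene was left out for low intensity, and no genome positions were used.

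The titles number the samples. IL-12 samples carry numbers from 2 to 4 (5 arrays) and from 5 to 6 (4 arrays), while the 3 samples without IL-12 carry 5, 7 and 8. No label says what the numbers mean. Both runs of numbers were treated as batches, because a difference between them would otherwise enter each comparison with untreated cells. All 12 arrays entered 1 linear model with 4 group means and a term for the number run, fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with 7 residual and 6.84 prior degrees of freedom per gene. Tests were two-sided. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 over all genes, with no minimum fold. Log2 changes of single genes are given ± SE from this model. Within-run values are differences of group means among arrays of 1 run. Python 3.11.15 with matplotlib 3.10.9 drew the plots.

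The comparisons were IL-12 2 h with untreated 2 h, IL-12 8 h with untreated 2 h, IL-12 8 h with IL-12 2 h, and untreated 2 h with baseline. In the last, the spread comes from the other groups, since there is 1 baseline array. Genes were named by a rule fixed before the data were examined, as were the model, the lists and most alternatives. It took the 12 largest rises and 12 largest falls among called genes with a given name, 6 and 6 for untreated against baseline, and up to 4 members of each list with the smallest p. It also took a panel of 14 genes whatever their result: Ifng, Il12rb1, Il12rb2, Stat4, Tbx21, Il18r1, Il18rap, Socs1, Socs3, Irf1, Gzmb, Il10, Il2ra and Gata3.

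The 26 lists held 472 genes, 420 of them measured. They covered the IL-12 and Th1 programme, cytokine signalling feedback, type I interferon-stimulated genes, and interferon-gamma-responsive GTPases with antigen presentation. Further lists covered cytotoxic effector, Th2, Th17, regulatory T cell, follicular helper, naive and quiescence, and T cell receptor response genes. Others covered G1/S and DNA replication, G2/M and mitosis, glycolysis, cholesterol biosynthesis, endoplasmic reticulum and amino acid stress, heat shock, and p53 and apoptosis genes. Markers of B cells, macrophages and monocytes, dendritic cells, neutrophils, CD8 T cells, NK cells, erythroid cells with platelets, and gamma-delta T cells stood for other cell types. The 24 lists with at least 5 measured genes were tested with limma's camera at its preset inter-gene correlation of 0.01 and adjusted over the 24 lists. The test was repeated with a correlation estimated for each list and with fry, which asks whether a list moves on balance in 1 direction without comparing it with other genes.

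The gene test was tested on simulated data for 19752 genes with 100 genes changed by a log2 of 0.5 and 100 by a log2 of 1. For IL-12 2 h against untreated it called 82% and 100% of them with 12 false calls, and for IL-12 8 h against untreated 77% and 100% with 11. For IL-12 8 h against 2 h it called 97% and 100% with 9 false calls, and for untreated against baseline 35% and 98% with 11. In the list test, simulated for IL-12 8 h against 2 h, the 1 list shifted by a log2 of 0.3 was called and 0 of the others were. In both simulations noise was independent between genes and the run effect was the same in all groups. They therefore do not show how many false calls arise when genes of a list vary together or when runs differ in their changes.

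Alternatives fixed beforehand were no run term, only arrays numbered 5 to 8, only the groups compared, baseline pooled with untreated, an intensity trend, robust moderation, and array weights. Quantile normalization, median centring, a filter on dim genes, the mean of a gene's probe sets, every probe set, an adjusted p under 0.1, at least 1.5-fold, each array left out in turn, and a replicate block completed them. The filter kept genes above the array median on at least 2 arrays. Added after the data had been seen were only arrays numbered 2 to 4, the mean of the macrophage and monocyte markers as a covariate, the baseline array placed with numbers 2 to 4, and a term that ties IL-12 2 h arrays 5 and 6 to untreated arrays 7 and 8. Chance sharing of calls between comparisons with the same untreated arrays was simulated with 100 draws of unchanged groups.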

Results

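Gene expression was measured in CD4+ T cells, the helper lineage of T lymphocytes, after 48 h of activation through the T cell receptor and CD28. IL-12 is a cytokine of antigen-presenting cells that acts through STAT4 and steers helper T cells towards the interferon-gamma-producing Th1 type. The samples followed the early response to it: 5 samples with IL-12 for 2 h, 4 with IL-12 for 8 h, 2 untreated for 2 h and 1 baseline sample. Values are log2 intensities of 19752 genes. The number of arrays limits the precision. The median SE of a log2 change was 0.095 for both comparisons with untreated cells, 0.069 for IL-12 8 h against 2 h and 0.13 for untreated against baseline. The labels do not say whether samples of a group came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical.

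Arrays of the same group and number run correlated at a median r of 0.998 across genes, which are not independent replicates. Arrays of the same group but other runs correlated at 0.992. Within numbers 5 to 8 the arrays did not part by group at 2 h. Untreated arrays 7 and 8 correlated at 0.9965, while untreated 7 with IL-12 2 h array 5 gave 0.9980 and untreated 8 with IL-12 2 h array 6 gave 0.9977. Principal component 1, with 42.1% of the variance, placed arrays numbered 2 to 4 and the baseline array below all others, and component 2, with 19.9%, placed IL-12 2 h arrays above IL-12 8 h arrays. The baseline array carries the number 5, yet it correlated at a median of 0.993 with arrays numbered 2 to 4 and 0.989 with those numbered 5 to 8. The number run changed 4795 genes, 2322 of them higher and 2473 lower in arrays numbered 2 to 4. Macrophage and monocyte markers differed with the run as well. The mean log2 intensity of 13 such markers was 7.19 and 7.06 in the untreated arrays, 6.95 and 7.10 in the IL-12 2 h arrays and 7.02 and 6.96 in the IL-12 8 h arrays of the same run. In arrays numbered 2 to 4 it lay between 6.53 and 6.62, and in the baseline array it was 6.77.

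**Figure D1:**
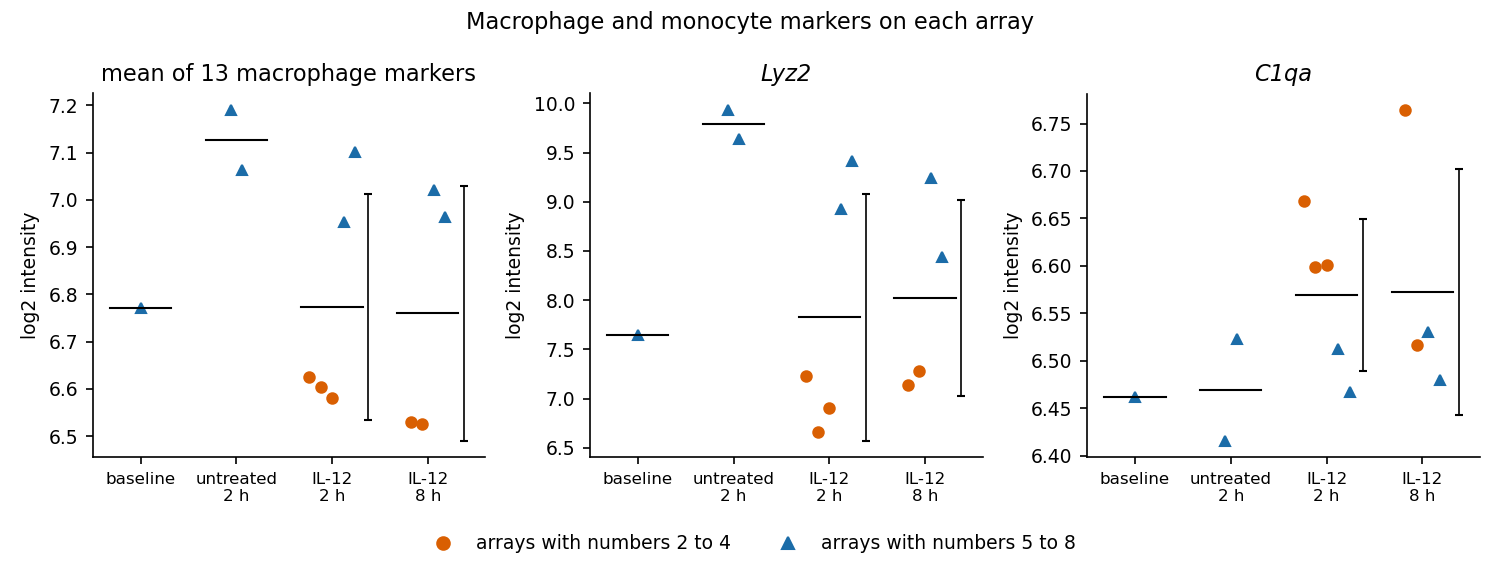
Log2 intensity on the vertical axes for the mean of 13 macrophage and monocyte markers and for Lyz2 and C1qa on each of the 12 arrays, by group; circles are arrays numbered 2 to 4, triangles those numbered 5 to 8, lines the group means and error bars the SD in groups of more than 2 arrays. The marker mean was 7.19 and 7.06 in the untreated arrays and between 6.53 and 6.62 in arrays numbered 2 to 4.

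The comparison of IL-12 2 h (n = 5) with untreated 2 h (n = 2) asks what IL-12 does at a matched time. Ifng, which encodes interferon-gamma, rose 3.83-fold (log2 1.94 ± 0.20, limma adjusted p = 0.0025). Both chains of the receptor for IL-18, a cytokine that acts together with IL-12, rose as well. Il18r1 rose 1.99-fold (log2 0.99 ± 0.13, adjusted p = 0.0102) and Il18rap 1.61-fold (log2 0.69 ± 0.08, adjusted p = 0.00561). Furin, a proprotein convertase gene known to respond to IL-12 and STAT4 in T cells, rose 1.83-fold (log2 0.87 ± 0.09, adjusted p = 0.0025). Jun, a subunit of the transcription factor AP-1, rose by a log2 of 0.92 ± 0.11 (adjusted p = 0.00362).

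Further rises were those of Serpinb5, a member of the serpin family (log2 0.99 ± 0.13, dimmer than the array median in both groups), Frmd4b (0.91 ± 0.12) and Cd86, a ligand of CD28 (0.81 ± 0.12). Sbno2 (0.69 ± 0.10), the adaptor gene Myd88 of IL-18 and Toll-like receptor signalling (0.60 ± 0.09), the ATP-gated channel gene P2rx7 (0.54 ± 0.08) and the microRNA gene Mir505 (0.54 ± 0.08) completed the genes taken by the rule. Adjusted p of these 7 genes lay between 0.00719 and 0.0249. Gnaq (0.49 ± 0.08) and D730005E14Rik (0.63 ± 0.10) also rose, with adjusted p = 0.0398 and 0.0484; they fell outside the rule and are named after their values were seen. In all, limma called 14 genes higher and 0 lower. At an unadjusted p under 0.05 the same fit had 539 higher and 432 lower genes. Together these were 971 of 19752 genes, no more than the share of 0.05 that unchanged genes alone would give. The smallest adjusted p of a lower gene was 0.218.

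Among arrays numbered 5 to 8 alone, where n = 2 in both groups, the 14 genes had log2 changes between 0.48 and 1.68, and limma called Ifng alone (log2 1.68 ± 0.12, adjusted p = 0.00174). The count of 14 became 2 without untreated array 7, 5 without untreated array 8, 9 without IL-12 2 h array 3, 9 without the run term and 4 with the macrophage marker mean as a covariate.

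The IL-12 and Th1 list shifted upward (camera adjusted p = 2.86e-09, and adjusted p = 0.0355 with an estimated correlation; median log2 0.18). Of its 22 measured genes 4 rose, 0 fell and 18 did not pass; adjusted over the list alone, 8 rose and 1 fell. The 4 were Ifng, Il18r1, Furin and Il18rap. Tbx21, the master regulator gene of the Th1 fate, had a log2 change of 0.56 ± 0.10 that missed the threshold (adjusted p = 0.0705). The IL-12 receptor genes Il12rb1 and Il12rb2 had log2 changes of -0.09 and 0.39, Stat4 had -0.12, Irf1 0.26, Il10 0.19, Gzmb -0.01 and Gata3 -0.11, with adjusted p between 0.796 and 0.999.

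Both lists of interferon-responsive genes shifted upward as sets, while no single member passed. The list of interferon-gamma-responsive GTPases and antigen presentation had 17 positive and 4 negative changes and a median of 0.25 (camera adjusted p = 2.87e-12, and adjusted p = 0.0355 with an estimated correlation). Of its 21 measured genes 0 passed over all genes, while 11 rose and 0 fell when adjusted over the list alone. Gbp5 and Irgm1, GTPases of defence against intracellular microbes, had log2 changes of 0.52 ± 0.09 (adjusted p = 0.0513) and 0.40 ± 0.09 (adjusted p = 0.357), and Irf8, a transcription factor gene, 0.47 ± 0.09 (adjusted p = 0.13). The type I interferon-stimulated list had 23 positive and 6 negative changes and a median of 0.22 (adjusted p = 2.43e-11, and adjusted p = 0.0355 with an estimated correlation). None of its 29 measured genes passed over all genes, and 8 rose and 0 fell when adjusted over the list alone. Usp18, a negative regulator of interferon signalling, had 0.47 ± 0.08 (adjusted p = 0.078) and Ifit3 0.63 ± 0.12 (adjusted p = 0.135). In arrays numbered 5 to 8 alone the medians of these lists were 0.23 and 0.18, and 0.11 for the Th1 list. Macrophage markers, which can answer to interferon as well, had a median log2 change of -0.04 (adjusted p = 0.172), and the myeloid lysozyme gene Lyz2 had -0.78 ± 0.24 (adjusted p = 0.796).

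A further 5 lists were called with the preset correlation only. Cytokine signalling feedback genes had a median of 0.16 (adjusted p = 3.03e-07, and adjusted p = 0.288 with an estimated correlation). Of 20 measured, 0 passed over all genes and 1 rose when adjusted over the list alone; Socs3, an inhibitor of cytokine receptors, had 0.49 ± 0.12 (adjusted p = 0.422), Socs1 0.27 and Il2ra 0.11. Th17 genes had a median of 0.14 (adjusted p = 0.0213, and adjusted p = 0.288 with an estimated correlation), with Ahr at 0.71 and Il23r at 0.34. Cholesterol biosynthesis genes lay lower, 20 of 20 with a negative change and a median of -0.19 (adjusted p = 4.24e-08, and adjusted p = 0.288 with an estimated correlation), among them Dhcr7 at -0.43 and Mvd at -0.37; in arrays numbered 5 to 8 the median was -0.07. G1/S and DNA replication genes had a median of -0.06 and glycolysis genes -0.08 (adjusted p = 0.0213 and 0.0387, and adjusted p = 0.552 for both with an estimated correlation), with Mcm3 at -0.19 and Tpi1 at -0.18. In the Th17, cholesterol, G1/S and glycolysis lists 0 genes passed, over all genes or adjusted over the list alone. Within arrays numbered 5 to 8 the feedback, Th17, G1/S and glycolysis medians were 0.07, 0.12, -0.02 and -0.08.

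Beside the macrophage markers, 15 lists were not called at 2 h. Camera adjusted p was 0.0835 for Th2 genes, 0.0868 for B cell markers, 0.151 for T cell receptor response genes, 0.172 for regulatory T cell genes, 0.272 for G2/M genes, 0.282 for follicular helper genes, 0.42 for stress genes of the endoplasmic reticulum and 0.466 for neutrophil markers. It was 0.5 for cytotoxic effector genes, 0.575 for naive and quiescence genes, 0.749 for dendritic cell markers, 0.949 for heat shock genes, NK cell markers and erythroid and platelet markers, and 0.966 for p53 and apoptosis genes. In these lists Jun, a T cell receptor response gene, was the only gene to pass; adjusted over the list alone, 2 T cell receptor response genes and 1 naive gene rose. The p53 and NK lists had a median, mean and test statistic that differed in sign. Too short to test, the CD8 list had a median of -0.11 over 2 genes and the gamma-delta list -0.02 over 4, with a mean of 0.07; 0 of these genes passed.

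**Figure D2:**
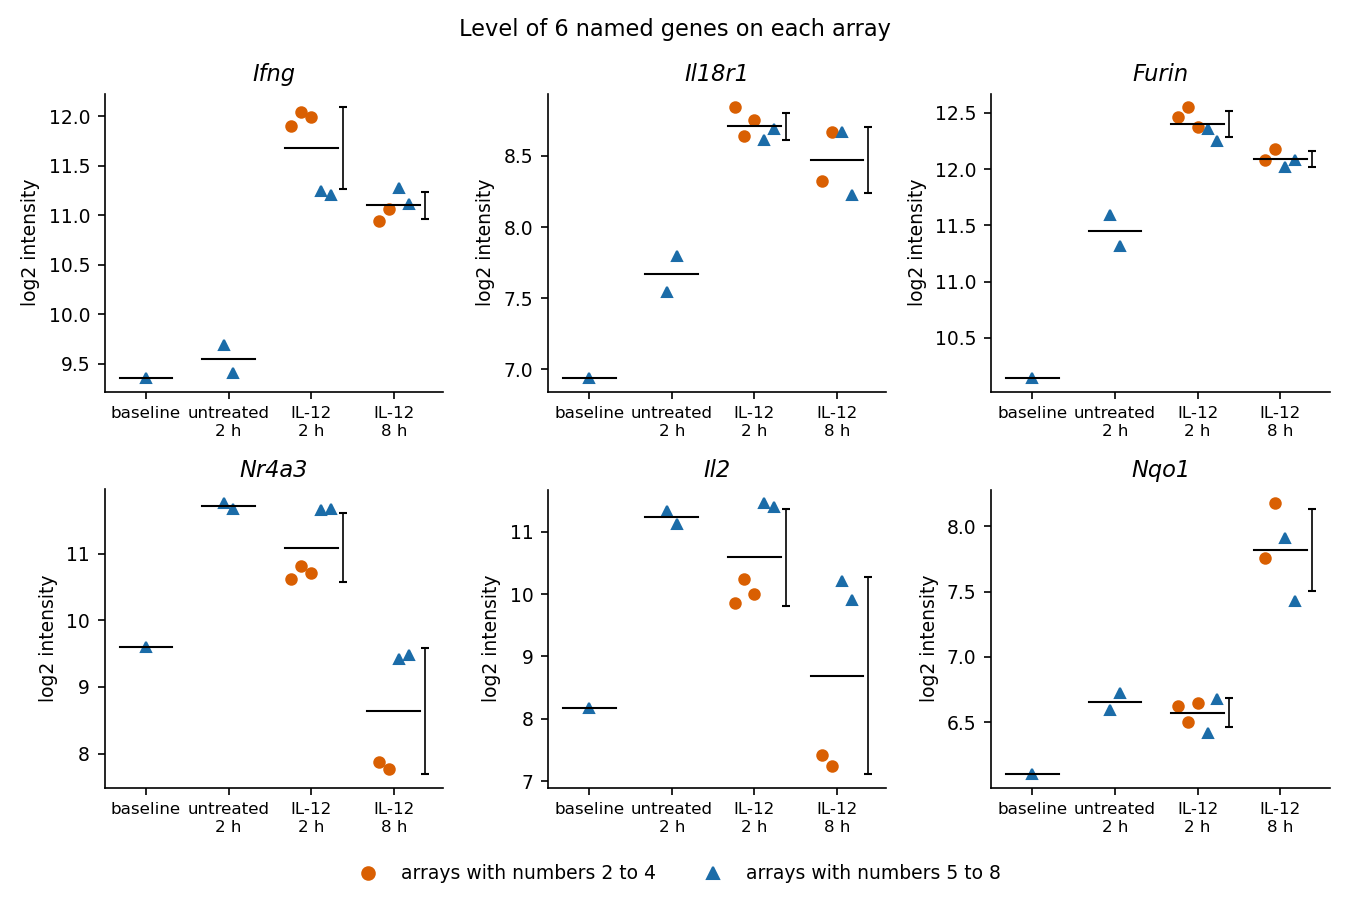
Log2 intensity on the vertical axes for Ifng, Il18r1, Furin, Nr4a3, Il2 and Nqo1 on each of the 12 arrays, by group; circles are arrays numbered 2 to 4, triangles those numbered 5 to 8, lines the group means and error bars the SD in groups of more than 2 arrays. The mean of Ifng was 11.68 with IL-12 for 2 h and 9.55 in untreated cells, and the IL-12 2 h arrays of the number runs stood apart.

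At 8 h of IL-12 (n = 4) against untreated 2 h (n = 2), IL-12 and 6 further hours in culture differ together. Genes of the early T cell receptor response lay far lower. Nr4a3, Nr4a1 and Nr4a2, orphan nuclear receptor genes that T cell receptor signals switch on, fell 5.46-fold, 4.82-fold and 3.01-fold (log2 -2.45 ± 0.15, -2.27 ± 0.14 and -1.59 ± 0.12, limma adjusted p = 9.1e-07, 1.07e-06 and 5.16e-06). Il2, the T cell growth factor gene, fell 2.91-fold (log2 -1.54 ± 0.27, adjusted p = 0.00636). Ifng was 2.62-fold higher (log2 1.39 ± 0.20, adjusted p = 0.00125; 1.65 within arrays numbered 5 to 8).

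Other large falls were those of the transcription factor genes Egr3 (log2 -1.90 ± 0.20) and Atf3 (-1.74 ± 0.22), of Nfkbid, an atypical inhibitor of NF-kappaB (-1.85 ± 0.11), and of the histone demethylase gene Kdm6b (-1.52 ± 0.09). Cd40lg, the helper signal for B cells (-1.52 ± 0.24), Muc1 (-1.44 ± 0.15), the adhesion gene Mpzl2 (-1.44 ± 0.09) and Spry1, an inhibitor of growth factor signalling (-1.43 ± 0.16), fell too. Adjusted p of these 8 genes lay between 9.1e-07 and 0.00244. On the side of the rises, Serpinb5 reached a log2 of 1.54 ± 0.13 and was dimmer than the array median in both groups. Nqo1, a quinone reductase gene of the response to oxidative and electrophilic stress, rose by 1.08 ± 0.15 and Atp6v0d2, a proton pump subunit gene, by 1.04 ± 0.15. Plac8 (0.94 ± 0.16), Sema4f (0.93 ± 0.13), the selenocysteine lyase gene Scly (0.91 ± 0.08), Ms4a4c (0.91 ± 0.12), P2rx7 (0.90 ± 0.08), Tmem106a (0.89 ± 0.10), Il18r1 (0.76 ± 0.13) and the RNA sensor gene Tlr7 (0.74 ± 0.10) rose too. Adjusted p of these 11 rises lay between 1.31e-05 and 0.00595. In all, 205 genes rose and 420 fell.

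The T cell receptor response list was lower as a whole, with a median log2 change of -0.76 (camera adjusted p = 1.36e-34, and adjusted p = 0.00096 with an estimated correlation). Of its 28 genes 16 fell, 1 rose and 11 did not pass; adjusted over the list alone, 26 fell and 1 rose. The riser was Jun, at 0.64. Follicular helper genes fell with it (median -0.28, adjusted p = 1.88e-05, and adjusted p = 0.0119 with an estimated correlation). Of 15 measured 4 fell, 0 rose and 11 did not pass, and 7 fell when adjusted over the list alone. They included Cd40lg, the IL-6 receptor gene Il6ra (-0.73 ± 0.08, adjusted p = 0.000123), the follicle-homing receptor gene Cxcr5 (-0.72 ± 0.11, adjusted p = 0.00212, dimmer than the array median) and the inhibitory receptor gene Pdcd1 (-0.57 ± 0.09, adjusted p = 0.00339). G2/M and mitosis genes rose, with 24 of 24 positive and a median of 0.25 (adjusted p = 3.3e-14, and adjusted p = 0.0119 with an estimated correlation). Of these 5 rose over all genes and 13 when adjusted over the list alone, among them the mitotic regulators Cdc20 (0.52 ± 0.07, adjusted p = 0.0011), Bub1b (0.48 ± 0.10, adjusted p = 0.013), Kif20a (0.40 ± 0.09, adjusted p = 0.0188) and Tpx2 (0.39 ± 0.08, adjusted p = 0.0172). Within arrays numbered 5 to 8 the medians of these lists were -0.74, -0.20 and 0.21. Macrophage markers had a median of -0.14 beside them (adjusted p = 0.0898), with Lyz2 at -0.78 ± 0.24 (adjusted p = 0.109).

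Th1 genes went both ways at 8 h, and the list was not called (median 0.05, adjusted p = 0.166). Of 22 measured 6 rose, 3 fell and 13 did not pass; adjusted over the list alone, 7 rose and 4 fell. Besides Ifng and Il18r1, Nkg7, a cytotoxic granule gene (0.65 ± 0.08, adjusted p = 0.000543), Furin (0.57 ± 0.09, adjusted p = 0.00346) and Tbx21 (0.40 ± 0.10, adjusted p = 0.0406) rose, while Tnfsf11, the RANK ligand gene, fell (-0.69 ± 0.07, adjusted p = 0.000112). Il18rap, Il12rb1, Il12rb2, Stat4, Irf1, Il10, Socs1, Socs3, Gzmb and Il2ra had log2 changes between -0.16 and 0.31 and adjusted p from 0.213 to 0.923.

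Type I interferon-stimulated genes (2 rose and 2 fell of 29, adjusted p = 0.153), interferon-gamma-responsive genes (0 rose and 2 fell of 21, adjusted p = 0.669) and feedback genes (1 rose and 0 fell of 20, adjusted p = 0.957) were not called either. Adjusted over the list alone, the counts were 8 rose and 3 fell, 1 rose and 3 fell, and 1 rose and 3 fell. Falls included Cd274, the gene of the checkpoint ligand PD-L1 (-0.97 ± 0.08, adjusted p = 2.17e-05), Irf8 (-0.45, adjusted p = 0.0147) and the RNA sensor gene Ifih1 (-0.63, adjusted p = 0.0175), and rises included Trim30a (0.46, adjusted p = 0.0035), Usp18 (0.39, adjusted p = 0.0192) and the kinase gene Pim2 (0.55, adjusted p = 0.0029).

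With the preset correlation only, Th2, Th17, regulatory T cell and glycolysis genes were called lower, with medians of -0.16, -0.11, -0.13 and -0.15. Within arrays numbered 5 to 8, the only run with untreated arrays, these medians were -0.06, -0.05, -0.03 and -0.18. The first 3 shifts thus rest largely on the run term. Adjusted p was 0.0277, 0.0291, 0.0291 and 0.0436, and adjusted p = 0.726, 0.389, 0.726 and 0.726 with an estimated correlation. Of 16 measured Th2 genes 3 fell, over all genes and over the list alone: Il4, the Th2 cytokine gene (-1.24 ± 0.19, adjusted p = 0.00244), the chemokine receptor gene Ccr8 (-1.12 ± 0.13, adjusted p = 0.000165) and the Th2 regulator gene Gata3 (-0.49 ± 0.12, adjusted p = 0.0391). Of 11 Th17 genes 1 fell on both counts, the chemokine receptor gene Ccr6 (-0.59 ± 0.13, adjusted p = 0.0186). Regulatory T cell genes had 2 falls of 16, and 4 when adjusted over the list alone, among them Lrrc32, an anchor of latent TGF-beta (-0.86 ± 0.13, adjusted p = 0.00244). Nt5e, which makes adenosine, was the other (-0.66 ± 0.11, adjusted p = 0.00306), and its log2 change was 0.059 when the baseline array was pooled with the untreated ones. Of 17 glycolysis genes the glucose transporter gene Slc2a1 rose (0.53 ± 0.11, adjusted p = 0.0147) and Tpi1 fell (-0.41 ± 0.08, adjusted p = 0.011); adjusted over the list alone 1 rose and 5 fell.

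The remaining 13 tested lists gave adjusted p between 0.0898 and 0.974. Single members of uncalled lists still fell or rose. Among cytotoxic effector genes the chemokine gene Ccl4 (-1.04 ± 0.10, adjusted p = 4.85e-05) and the death ligand gene Fasl (-1.22 ± 0.12, adjusted p = 6.74e-05) fell and the protease gene Ctsw rose (0.64 ± 0.09, adjusted p = 0.00138), so that 1 of 24 rose and 2 fell on both counts. The NK cell marker Klrb1c fell (-0.88 ± 0.10, adjusted p = 0.000279), the only NK marker of 8 to pass, and was dimmer than the array median in both groups. Median, mean and test statistic differed in sign for the interferon-gamma-responsive, feedback, cytotoxic, cholesterol, B cell and neutrophil lists.

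Within arrays numbered 5 to 8 alone, 320 genes were called. The count of 625 became 300 without untreated array 7, 267 without untreated array 8, 243 without the run term, 90 with the baseline array pooled with the untreated ones and 99 with the macrophage marker mean as a covariate. Il2, Muc1 and Mpzl2 lay at log2 intensities of 8.17, 6.52 and 6.82 in the baseline array, far below the untreated arrays, so pooling it made their falls much smaller. The analysed samples hold no untreated culture of 8 h.

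**Figure D3:**
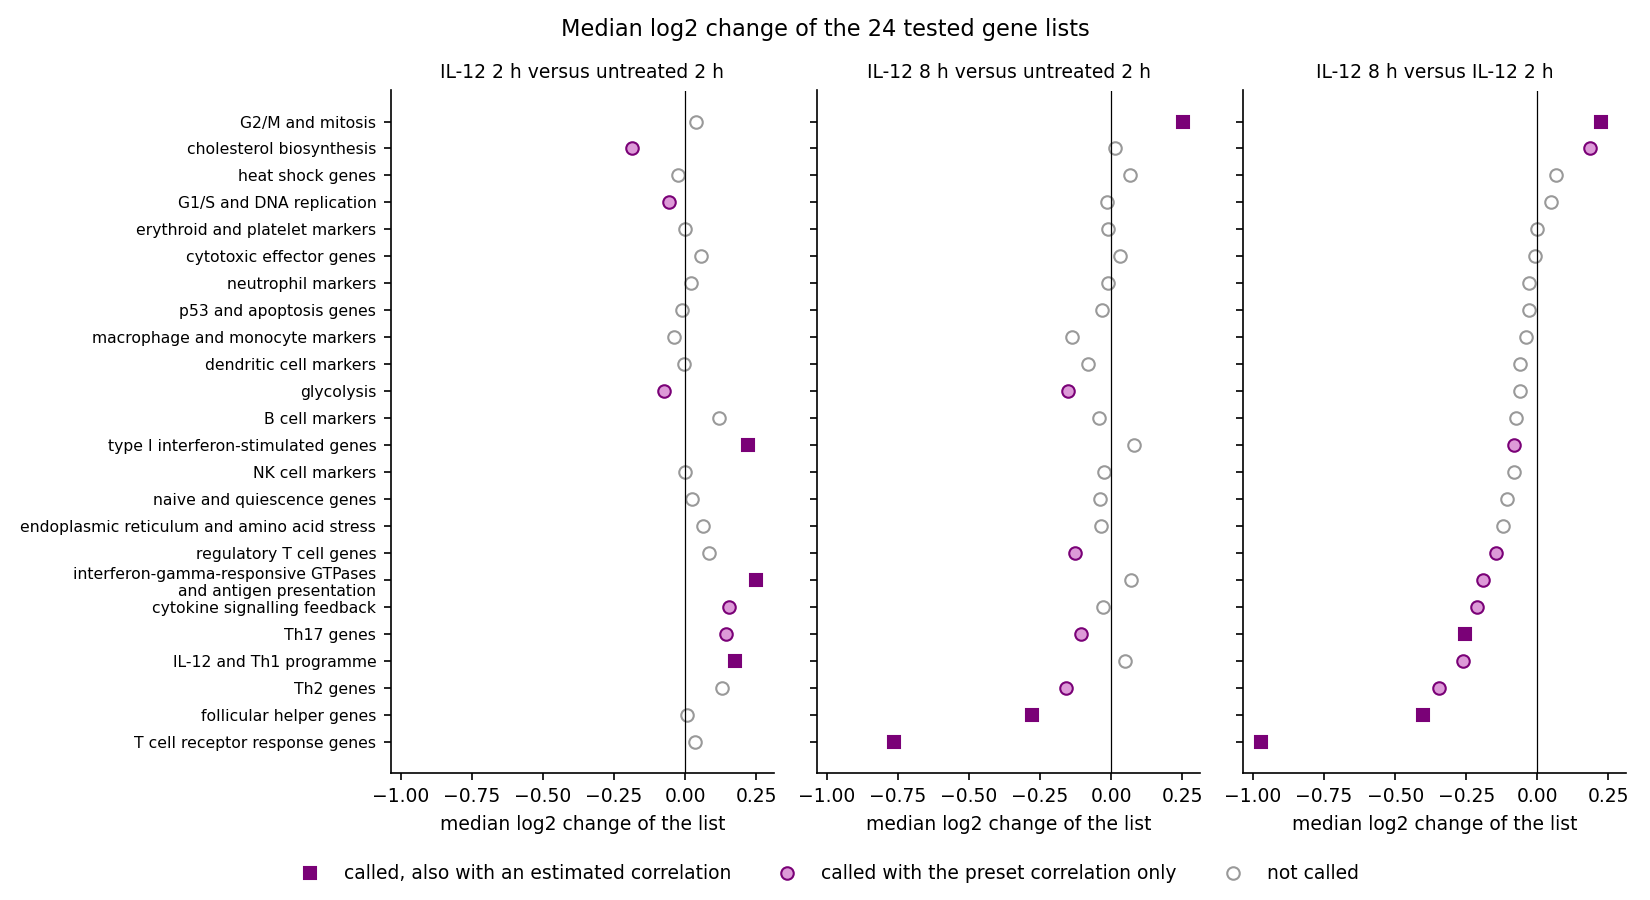
Median log2 change (horizontal axes) of the 24 tested lists in 3 comparisons; squares are lists called by camera with the preset and the estimated correlation, filled circles those called with the preset only, and open circles lists not called. T cell receptor response genes had medians of 0.04 at 2 h and -0.76 at 8 h against untreated cells, and -0.97 between the IL-12 times.

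The same 2 untreated arrays served both comparisons. Of the 14 genes that rose at 2 h and the 205 that rose at 8 h, 9 were shared: Ifng, Il18r1, Furin, Jun, Serpinb5, Sbno2, Myd88, P2rx7 and D730005E14Rik. Independent lists of these sizes would share 0.145 genes, and unchanged groups simulated against the same untreated arrays shared a mean of 0.02 and at most 1 over 100 draws. Since no gene was changed in that simulation, few could be called in it at all. Its count therefore does not show how much sharing the common untreated arrays give among called genes. No gene rose at 2 h and fell at 8 h, where independent lists would give 0.298. Across all genes the log2 changes correlated at r = 0.292, below the 0.737 of the simulated unchanged groups, and had the same sign in 63.8% of genes against 76.4%. Their covariance was 0.00593 against a simulated 0.00804. In the simulation the runs did not differ in the change from 2 h to 8 h, whereas in the data they did for 387 genes. The lower observed values therefore decide nothing about sharing. Genes are not independent replicates. With the untreated arrays used apart, a split made after the results were seen, 5 rises at 2 h against array 7 and 74 at 8 h against array 8 shared 2 genes, and the 2 and 67 of the reverse use shared 1, where 0.0187 and 0.00678 would be shared if independent. With so few rises at 2 h this split bounds little, and part of the excess may come from the shared controls. The count of 9 became 2 without untreated array 7, 3 without untreated array 8, 5 without IL-12 8 h array 5 and 1 within arrays numbered 5 to 8.

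Between IL-12 2 h (n = 5) and IL-12 8 h (n = 4), where both number runs hold both groups, T cell receptor response genes fell. Nr4a3 was 5.99-fold lower at 8 h (log2 -2.58 ± 0.11, limma adjusted p = 1.22e-08), with -2.90 within arrays numbered 2 to 4 and -2.21 within those numbered 5 to 8. Il2 was 4.29-fold lower (log2 -2.10 ± 0.20, adjusted p = 1.32e-05; -2.71 and -1.37 by run). Nqo1 showed the largest rise, 2.39-fold (log2 1.26 ± 0.11, adjusted p = 5.79e-06; 1.37 and 1.11 by run). Ifng was 1.46-fold lower at 8 h (log2 -0.55 ± 0.14, adjusted p = 0.0227), with -0.98 within arrays numbered 2 to 4 and -0.03 within those numbered 5 to 8. The runs differed in this change by -0.95 ± 0.12 (adjusted p of the run-by-time term = 0.00179).

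The other large falls were Atf3 (-2.06 ± 0.16), Nr4a1 (-1.98 ± 0.10), Mpzl2 (-1.69 ± 0.06), Egr3 (-1.64 ± 0.15), Nfkbid (-1.59 ± 0.08) and Kdm6b (-1.47 ± 0.07). With them fell the cytokine and chemokine genes Il3 (-1.67 ± 0.18), Lif (-1.60 ± 0.11), Cxcl10 (-1.56 ± 0.16) and Il4 (-1.48 ± 0.14). Adjusted p of these 10 genes lay between 4.59e-09 and 3.87e-05. The size of several falls differed between the runs: within arrays numbered 2 to 4 and within those numbered 5 to 8, Atf3 changed by -2.56 and -1.45, Il3 by -2.21 and -1.02, Cxcl10 by -2.05 and -0.98, Il4 by -1.88 and -1.001, Lif by -1.94 and -1.19, Nr4a1 by -1.67 and -2.35 and Egr3 by -1.19 and -2.18. Among the rises were Atp6v0d2 (0.97 ± 0.11), the glutaredoxin gene Glrx (0.90 ± 0.09), and Cyp1a1, the cytochrome gene that the aryl hydrocarbon receptor switches on (0.87 ± 0.24). For Cyp1a1, IL-12 8 h array 5 lay at a log2 intensity of 8.82 and the other 8 h arrays between 6.83 and 7.36, and the call held in 18 of 27 settings. Plac8 (0.85 ± 0.11; 1.17 and 0.47 by run), Dglucy (0.82 ± 0.09), the steroid-synthesis cytochrome gene Cyp11a1 (0.81 ± 0.07), Narf (0.76 ± 0.14; 1.15 and 0.29 by run), the thromboxane receptor gene Tbxa2r (0.73 ± 0.08), Arhgef18 (0.72 ± 0.07) and Frmd8 (0.72 ± 0.07) rose too. Adjusted p of these 10 rises lay between 3.96e-06 and 0.031. The carbonic anhydrase gene Car5b rose by 0.80 ± 0.17 (adjusted p = 0.00752), with 1.35 within arrays numbered 2 to 4 and 0.14 within those numbered 5 to 8.

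In all, 1239 genes rose and 1257 fell, 1 of them by at least 2-fold upward and 55 downward. With each array centred on its median the split was 1662 and 1025. Runs were also set against each other on genes called in 1 run and measured in the other, a test chosen after the results were seen. Of the genes called in arrays numbered 2 to 4 alone, 77.1% had the same sign in arrays numbered 5 to 8, with a median size of 0.35 in the first and 0.15 in the second. In the reverse direction 91.7% had the same sign, with median sizes of 0.65 and 0.48, and 58.9% of all genes did. Across all genes the changes of the runs correlated at r = 0.463. With 1 run at a time, 3225 genes were called in arrays numbered 2 to 4 and 363 in those numbered 5 to 8. The count became 1525 without IL-12 8 h array 3, 871 without the run term and 1253 with the macrophage marker mean as a covariate. The covariate left the 2496 genes at 97.4% of their median size and all 2496 signs as they were, while the median SE went from 0.067 to 0.080. This decides little, because the marker mean differed little between the IL-12 times within either run.

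**Figure D4:**
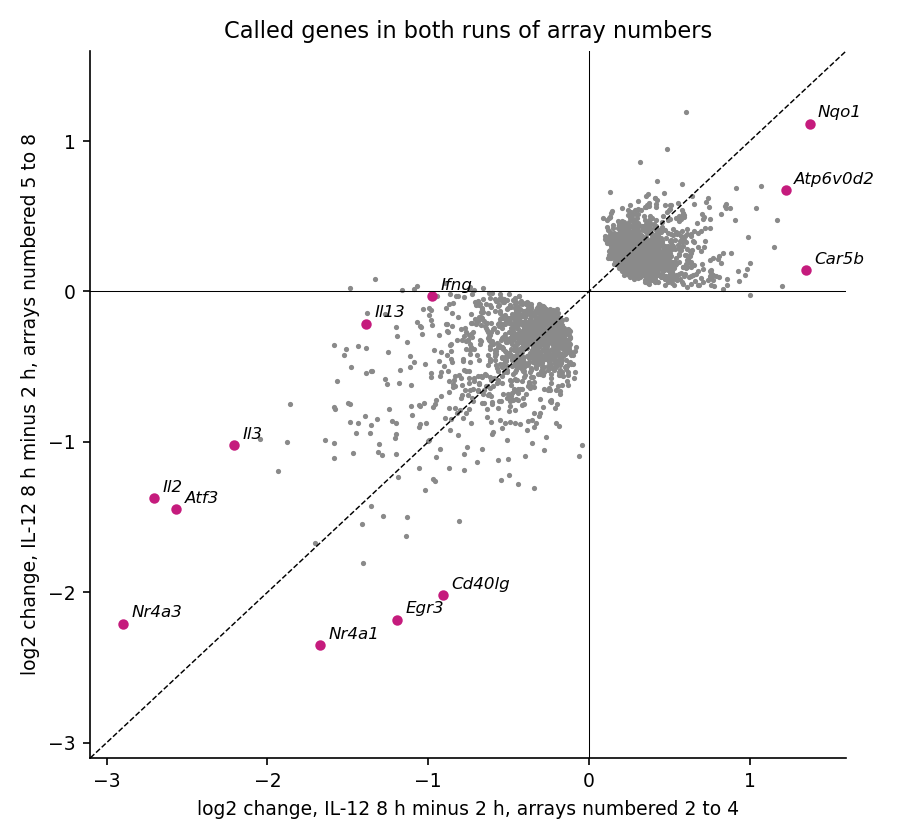
Log2 change from IL-12 2 h to IL-12 8 h within arrays numbered 2 to 4 (horizontal axis) and within arrays numbered 5 to 8 (vertical axis); each point is 1 of the 2496 genes called, named genes are coloured and the dashed line marks equal change. Nr4a3 changed by -2.90 and -2.21 and Ifng by -0.98 and -0.03.

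T cell receptor response genes fell almost throughout, 26 of 28 over all genes and 27 when adjusted over the list alone, and 0 rose (median -0.97, camera adjusted p = 7e-36, and adjusted p = 0.000851 with an estimated correlation; -1.03 and -0.83 by run). Follicular helper genes fell, 9 of 15 with 1 riser, or 11 and 1 adjusted over the list alone (median -0.40, adjusted p = 8.14e-07, and adjusted p = 0.00895 with an estimated correlation; -0.50 and -0.17 by run). Examples were Cd40lg (-1.42 ± 0.17, adjusted p = 0.00011; -0.91 and -2.02 by run), Pdcd1 (-0.63 ± 0.07, adjusted p = 3.49e-05) and Il6ra (-0.61 ± 0.06, adjusted p = 1.07e-05). Th17 genes fell in 5 of 11 cases, 9 adjusted over the list alone (median -0.25, adjusted p = 1.31e-05, and adjusted p = 0.0375 with an estimated correlation; -0.26 and -0.24 by run), led by Ahr, the aryl hydrocarbon receptor gene (-1.02 ± 0.16, adjusted p = 0.000728; -1.52 and -0.43 by run). G2/M genes rose, 13 of 24 with 0 falls, 17 adjusted over the list alone (median 0.23, adjusted p = 6.06e-11, and adjusted p = 0.0183 with an estimated correlation; 0.28 and 0.17 by run), among them Cdc20 (0.54 ± 0.05, adjusted p = 1.92e-05) and Bub1b (0.51 ± 0.07, adjusted p = 0.000297). Macrophage markers had a median of -0.04 between these times, with 0 of 13 called (adjusted p = 0.39).

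Of the lists raised at 2 h, Th1, interferon-responsive and feedback genes were called lower at 8 h than at 2 h with the preset correlation, and the Th1 and feedback medians fell mainly in arrays numbered 2 to 4. Th1 genes had 10 falls and 4 rises of 22, or 12 and 4 adjusted over the list alone (median -0.26, adjusted p = 0.00423, and adjusted p = 0.265 with an estimated correlation; -0.32 and -0.05 by run). Il18rap (-0.58 ± 0.06, adjusted p = 3.77e-05), Irf1 (-0.35 ± 0.06, adjusted p = 0.00276) and Il10 (-0.35 ± 0.08, adjusted p = 0.0105) fell, Nkg7 rose by 0.52 ± 0.06 (adjusted p = 8.21e-05), and Tbx21 at -0.16 did not pass (adjusted p = 0.2). Interferon-gamma-responsive genes had 9 falls and 2 rises of 21, or 11 and 3 adjusted over the list alone (median -0.19, adjusted p = 0.000336, and adjusted p = 0.265 with an estimated correlation; -0.17 and -0.15 by run), with Cd274 at -1.20 ± 0.06 (adjusted p = 5.39e-08) and Irf8 at -0.92 ± 0.07 (adjusted p = 9.59e-07). Type I interferon-stimulated genes had 8 falls and 2 rises of 29, or 9 and 2 adjusted over the list alone (median -0.08, adjusted p = 0.0167, and adjusted p = 0.415 with an estimated correlation; -0.06 and -0.02 by run). Feedback genes had 9 falls and 1 rise of 20, or 10 and 2 adjusted over the list alone (median -0.21, adjusted p = 0.0044, and adjusted p = 0.551 with an estimated correlation). The feedback median was -0.34 within arrays numbered 2 to 4 and 0.05 within those numbered 5 to 8. Socs1 fell (-0.38 ± 0.10, adjusted p = 0.0227), with -0.66 and -0.05 by run and a run-by-time adjusted p of 0.0175.

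Th2 genes had 8 falls and 2 rises of 16, or 10 and 2 adjusted over the list alone (median -0.35, adjusted p = 3e-04, and adjusted p = 0.406 with an estimated correlation; -0.55 and -0.13 by run), with Ccr8 at -1.10 ± 0.09 (adjusted p = 3.82e-06) and Gata3 at -0.38 ± 0.09 (adjusted p = 0.00994). Regulatory T cell genes had 6 falls and 0 rises of 16, or 8 and 1 adjusted over the list alone (median -0.14, adjusted p = 0.000911, and adjusted p = 0.415 with an estimated correlation; -0.32 and -0.09 by run), with Nt5e at -0.78 ± 0.08 (adjusted p = 2.01e-05). Cholesterol biosynthesis genes had 5 rises and 0 falls of 20, or 6 and 0 adjusted over the list alone (median 0.18, adjusted p = 3e-04, and adjusted p = 0.415 with an estimated correlation). Their median was 0.32 within arrays numbered 2 to 4 and -0.03 within those numbered 5 to 8, and Dhcr7 rose by 0.60 ± 0.10 (adjusted p = 0.00154), with 0.88 and 0.25 by run. The other 13 lists gave adjusted p between 0.0729 and 0.975; the erythroid and platelet list had a median and mean that differed in sign.

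The last comparison set untreated 2 h cells (n = 2) against the baseline array (n = 1). Muc1, a mucin gene (log2 3.52 ± 0.20, 11.5-fold, limma adjusted p = 2.71e-07), Emp1 (3.11 ± 0.20), Il2 (3.06 ± 0.36), Cd40lg (2.60 ± 0.31), Slc6a12 (2.55 ± 0.30) and Mpzl2 (2.54 ± 0.11) were higher. The platelet chemokine genes Ppbp (-2.88 ± 0.62) and Pf4 (-1.96 ± 0.23), the red cell carbonic anhydrase gene Car1 (-2.51 ± 0.22), the small nucleolar RNA genes Snora33 (-2.63 ± 0.36) and Snora75 (-2.13 ± 0.26) and Gpr33 (-2.30 ± 0.43) were lower. Adjusted p of these 12 genes lay between 4.28e-08 and 0.00862. With the baseline array placed with numbers 2 to 4, 6 of them were no longer called: Il2 (1.06), Cd40lg (1.42), Slc6a12 (0.69), Ppbp (-1.19), Pf4 (-0.89) and Gpr33 (-1.02). From the panel, Il10 (0.97 ± 0.15, adjusted p = 0.000829), Il18r1 (0.73 ± 0.18, adjusted p = 0.0164) and Il18rap (0.56 ± 0.11, adjusted p = 0.00539) were higher, Stat4 was lower (-0.58 ± 0.10, adjusted p = 0.00235) and Ifng had 0.19 ± 0.26 (adjusted p = 0.728). In all, limma called 1240 genes higher and 782 lower, with no replicate of the baseline array.

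T cell receptor response genes were higher in 19 of 28 cases and lower in 0, or 23 and 0 adjusted over the list alone (median 0.85, camera adjusted p = 5.33e-25, and adjusted p = 0.00178 with an estimated correlation). Follicular helper genes were higher in 11 of 15 cases and lower in 1, or 13 and 1 adjusted over the list alone (median 0.81, adjusted p = 4.92e-11, and adjusted p = 0.00178 with an estimated correlation). The p53 and apoptosis genes were higher in 6 of 16, or 9 adjusted over the list alone (median 0.40, adjusted p = 1.84e-07, and adjusted p = 0.014 with an estimated correlation). Markers of other cells differed beside them. Macrophage markers had 3 higher of 13, on both counts (median 0.22, adjusted p = 0.00244, and adjusted p = 0.139 with an estimated correlation), with Lyz2 at 2.13 ± 0.32 (adjusted p = 0.0007). B cell markers had 3 lower of 13, or 4 adjusted over the list alone (median -0.32, adjusted p = 0.000125, and adjusted p = 0.0919 with an estimated correlation), with Ms4a1 at -1.44 ± 0.12 (adjusted p = 7.43e-06). Erythroid and platelet markers had 3 lower of 7, or 4 adjusted over the list alone (median -0.56, adjusted p = 0.00163, and adjusted p = 0.162 with an estimated correlation). Of 8 NK cell markers 2 were higher, on both counts (adjusted p of the list = 0.0585), Ncr1 by 0.46 and Klrb1c by 0.56. Of 10 dendritic cell markers 1 was higher, Itgax by 0.43, and of 2 CD8 T cell markers 1, Cd8b1 by 0.54. The T cell receptor response, follicular helper and macrophage lists were called lower in arrays numbered 2 to 4 (medians -0.276, -0.395 and -0.315). The erythroid and platelet list was called higher there (median 0.214), and the p53 and B cell lists were not called. The baseline array correlated more closely with those arrays. For the lists called there, a run difference cannot be told apart from 2 h of culture. The marker genes of this paragraph are named after their values were seen.

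Glycolysis genes were lower in 10 of 17 cases and higher in 0, or 13 and 0 adjusted over the list alone (median -0.57, adjusted p = 6.65e-11, and adjusted p = 0.0726 with an estimated correlation). Type I interferon-stimulated genes were lower in 13 of 29 and higher in 1, or 16 and 2 adjusted over the list alone (median -0.40, adjusted p = 2.36e-07, and adjusted p = 0.0726 with an estimated correlation). The median of this list was also 0.47 higher in arrays numbered 2 to 4, with which the baseline array correlated more closely. A run difference cannot be told apart from 2 h of culture here. G2/M genes were lower in 4 of 24, or 5 adjusted over the list alone (adjusted p = 0.0012, and adjusted p = 0.139 with an estimated correlation). In 21 endoplasmic reticulum and amino acid stress genes 5 were higher and 1 lower, in 17 naive genes 5 and 3, in 24 cytotoxic genes 3 and 1 and in 16 regulatory T cell genes 2 and 1. Adjusted over the list alone the counts were 11 and 4, 7 and 3, 3 and 1, and 5 and 2. Stress, naive, cytotoxic and regulatory T cell genes were called higher with the preset correlation only (adjusted p = 0.00245, 0.00664, 0.041 and 0.0444, and adjusted p = 0.326, 0.175, 0.187 and 0.507 with an estimated correlation). Of these, the stress, naive and regulatory T cell lists were called lower in arrays numbered 2 to 4 (camera adjusted p = 3.11e-05, 0.00112 and 0.00651). The limit given for the interferon list holds for them too. The cytotoxic list was not called between the runs (adjusted p = 0.336). The other 11 lists gave adjusted p between 0.0585 and 0.939, and median, mean and test differed in sign for Th2 genes and dendritic cell markers. The count of 2022 genes became 204 with the baseline array placed with numbers 2 to 4, 115 without the run term and 29 with the macrophage marker mean as a covariate. The covariate left the median size at 105% and 2017 signs as they were, while the median SE went from 0.12 to 0.28.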

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

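The test between number runs and the count of probe sets without a single gene name were chosen only after the data had been seen; the search for outlying arrays and the comparison with other groupings were set before the data were examined.

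The change against untreated cells differed between IL-12 8 h and IL-12 2 h for 2496 genes, with Nr4a3, Il2 and Atf3 falling most among the named genes. To ask whether any grouping of the 9 IL-12 arrays would give as many, 100 of the 126 possible splits into 5 and 4 arrays were drawn. The count was reached by 2 of them, the real one included. The other, with 3174 genes, set the 4 arrays numbered 5 to 8 against the 5 numbered 2 to 4, so it was the number run itself. The next highest, with 1255 and 930 genes, joined the 2 h arrays numbered 2 to 4 with 2 h array 6 or 5, so they followed time and run in part. Among 47 drawn splits with 2 arrays of each run in the smaller group, the highest count was 5. Among the drawn splits, only the split by number run gave more genes than the real one. Its fit held no run term, because run and group coincided there, while the fit of the real split did. Splits that mix the times put the time difference into the spread, which lowers their counts. Since it is unknown whether the samples are independent, chance differences between cultures are not excluded by these counts. Within arrays numbered 2 to 4 and within those numbered 5 to 8, 3225 and 363 genes were called.

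The number runs differed in how far genes moved between 2 h and 8 h: a run-by-time term in the 9 IL-12 arrays was called by limma for 387 genes, and 2871 passed at an unadjusted p under 0.05. Ifng fell by 0.98 within arrays numbered 2 to 4 and by 0.03 within those numbered 5 to 8. T cell receptor response genes were among them in 12 of 28 cases, with a steeper fall in arrays numbered 2 to 4 for 10 and the reverse for 2. Of 20 cholesterol biosynthesis genes 9 rose more steeply in arrays numbered 2 to 4. The runs differ by an unknown feature, so the pooled changes from 2 h to 8 h of these genes average over unlike changes. Untreated arrays carry numbers 5 to 8 only, so comparisons with them take the run term from IL-12 arrays, where it is not constant for these genes. On untreated arrays 7 and 8 and on 8 h arrays 5 and 6, Il2 lay at 11.34, 11.13, 10.21 and 9.90. Nr4a1 lay at 12.19, 12.13, 9.69 and 9.73. The gap within this run was smaller than the model's change for Il2 and larger for Nr4a1.

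Il2ra, the gene of the IL-2 receptor alpha chain, stood apart on IL-12 8 h array 6, at a log2 intensity of 13.52 where the other 3 arrays lay between 13.44 and 13.45. Dixon's ratio test at 95% was made on 132 groups of arrays and found 1 such case, where 6.6 would be expected by chance. The distance was small in absolute terms and the array was kept.

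Probe sets without a single gene name were left out of the gene tests. Tested apart with the same model, 1 of 3497 was called between IL-12 2 h and untreated cells, 68 between IL-12 8 h and untreated cells, 275 between IL-12 8 h and 2 h, and 214 between untreated cells and baseline. Rises and falls among them were 1 and 0, 32 and 36, 123 and 152, and 105 and 109. Transcripts behind them were not identified here.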

How the results depend on the processing

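The macrophage covariate, the placing of the baseline array with numbers 2 to 4, the term tying 2 h arrays across groups and the fit of arrays numbered 2 to 4 alone were chosen after the results had been seen. The 14 genes of IL-12 2 h against untreated became 9 without the run term, 1 within arrays numbered 5 to 8, 9 with array weights and 4 with the macrophage covariate. With 1 array left out the count lay between 2 (untreated 7) and 14 (baseline), with 5 without untreated 8 and 9 without IL-12 2 h array 3. Its 8 lists became 3 with an estimated correlation and 3 with fry, and between 6 (without untreated 8) and 13 (without IL-12 2 h array 6). The 625 genes of IL-12 8 h against untreated became 979 at an adjusted p under 0.1, 206 at 1.5-fold or more, 243 without the run term, 320 within arrays numbered 5 to 8, 90 with the baseline array pooled with the untreated ones and 99 with the macrophage covariate. Leaving out an array gave between 267 (untreated 8) and 663 (IL-12 2 h array 6), with 300 without untreated 7. Its 7 lists became 3 with an estimated correlation, 3 with fry, 4 with the macrophage covariate, and between 4 (without untreated 8) and 9 (without IL-12 8 h array 6). With the baseline array pooled, Nt5e turned from a log2 of -0.66 to 0.059 in this comparison, the only called result of a named gene to change sign. The 2496 genes of IL-12 8 h against 2 h became 265 at 1.5-fold or more, 871 without the run term, 363 within arrays numbered 5 to 8, 1227 with the baseline array pooled, 1253 with the macrophage covariate, and between 1525 (without IL-12 8 h array 3) and 2536 (without either untreated array). Its 11 lists became 4 with an estimated correlation and 6 within arrays numbered 5 to 8. The 2022 genes of untreated against baseline became 1011 at 1.5-fold or more, 115 without the run term, 29 with the macrophage covariate and 204 with the baseline array placed with numbers 2 to 4. The 9 shared rises became 4 without the run term, 1 within arrays numbered 5 to 8, 5 with the baseline array pooled, 1 with the macrophage covariate, and between 2 (without untreated 7) and 9 (without the baseline array), with 3 without untreated 8 and 5 without IL-12 8 h array 5. The cause of these differences was not tested.

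Numbers 2, 3, 5 and 6 occur in both IL-12 groups, and a replicate block on them left 1246 genes. Deviations from group means correlated between arrays sharing a number at 0.365, 0.30, 0.519 and 0.372 across genes, but 1 of 4 arrays at 8 h correlated best with its own number. These deviations hold the number run. With run means removed too, the values were -0.26, -0.18 and, for 5 and 6 alike because they mirror each other, 0.03, a hint from the data that the run, not the number, ties these samples. IL-12 and untreated samples share no numbers. In their values, IL-12 2 h array 5 correlated with untreated array 7 at 0.558 and with untreated array 8 at -0.558, which mirror each other too. With 2 h arrays 5 and 6 tied to untreated arrays 7 and 8, a tie read from these values and not from labels, 14 genes and 8 lists were called, 13 of the genes as before, and Tbx21 passed (adjusted p = 0.0246). Of 179 called results for named genes, 47 kept their call in every setting, among them the rise of Ifng at 2 h. Both groups lay below the array median for 1 of the 14, 55 of the 625, 244 of the 2496 and 240 of the 2022 called genes.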

Other observations

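All tests in this part were chosen only after the results had been seen.

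The number runs differed in several gene lists and in single genes outside them. Of 29 type I interferon-stimulated genes 23 were higher and 1 lower in arrays numbered 2 to 4, with a median log2 difference of 0.47 (camera adjusted p = 4.05e-12, and adjusted p = 0.0278 with an estimated correlation). Ifi27l2a (0.93 ± 0.05, limma adjusted p = 2.49e-07), Rnf213 (0.86 ± 0.06, adjusted p = 5.72e-07) and Rtp4 (1.01 ± 0.09, adjusted p = 5.72e-06) were examples. The genes with the smallest p were lower in arrays numbered 2 to 4: Igfbp7 (-1.99 ± 0.06, adjusted p = 9.32e-11), Atp1b1 (-1.80 ± 0.09), Nt5e (-1.48 ± 0.08) and Clec4e (-2.35 ± 0.13). The chemokine genes Cxcl9 (1.87 ± 0.14, adjusted p = 1.6e-06) and Ccl5 (1.12 ± 0.10, adjusted p = 5.28e-06) and the B cell gene Ms4a1 (1.03 ± 0.07, adjusted p = 5.2e-07) were higher there too. T cell receptor response genes were lower in 15 of 28 cases and higher in 1 (median -0.28, adjusted p = 3.67e-09, and adjusted p = 0.0278 with an estimated correlation). Follicular helper genes were lower in 10 of 15 and higher in 1 (median -0.40, adjusted p = 2.79e-05, and adjusted p = 0.0278 with an estimated correlation). Macrophage markers were lower in 8 of 13 (adjusted p = 2.3e-05, and adjusted p = 0.0594 with an estimated correlation). No label says why the runs differ.

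Of the lists, endoplasmic reticulum and amino acid stress genes held 9 of the genes whose change from 2 h to 8 h differed between the runs, 8 with a lower value in arrays numbered 2 to 4 and 1 with a higher one, and cytokine feedback genes held 6, all lower. Among the single genes with the smallest p, Il24 changed by -1.50 within arrays numbered 2 to 4 and 0.19 within those numbered 5 to 8, Osm by -1.33 and 0.08, Il13 by -1.38 and -0.21, and Lta by -1.58 and -0.36. Socs2, an inhibitor of cytokine signalling, changed by -1.23 and 0.14, the costimulatory receptor gene Cd40 by -1.48 and 0.02 and the transcription factor gene Irf4 by -1.51 and -0.38. The amino acid transporter genes Slc6a9 (-1.29 and 0.75) and Slc1a4 (-1.33 and 0.20) fell in the first run alone. Adjusted p of the run-by-time term for these 9 genes lay between 5.94e-05 and 0.000355.

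Positions were set on a scale from 0 at the untreated level to 1 at that level shifted by the model's run term. Position 1 is thus not the measured level of arrays numbered 2 to 4, which also differ from untreated cells in IL-12. For Nr4a3, at position 1.68, the baseline array lay at 9.59 and arrays numbered 2 to 4 at a mean of 9.55. The baseline array, number 5, had a median position of 1.02 over 66 genes that parted the runs at least 2-fold. It lay below 0.25 for 9.09% of them, where the arrays numbered 2 to 4 did so for 5.81% to 18.1% of such genes. Those arrays were scaled by the run difference at the other IL-12 time, on other sets of 86 and 94 genes. Their median positions were 0.60 to 0.69, and they lay past 0.75 for 31% to 47% of genes, against 74% for the baseline array. On the share below 0.25 alone, a shared preparation with those arrays is a candidate explanation that fits. It does not cover every gene: Ctsg, Cpa3, Mpo and Prss34, granule genes of mast cells and other myeloid cells, lay between -0.21 and 0.05, with Gadd45g and Oasl1 also near the untreated level, and Mpzl2 (2.45), Cd40lg (2.21) and Pdgfb (2.18) lay far past 1. Culture for 2 h could instead have moved the untreated arrays away from baseline. Genes at least 2-fold higher than baseline in 1 untreated array had a median log2 change of -0.50 and -0.42 from the other untreated array to IL-12 8 h within arrays numbered 5 to 8, so they moved with later culture or IL-12, and that explanation stays open because the baseline array has no counterpart in either run.

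Untreated arrays carried more macrophage marker signal than arrays numbered 2 to 4, so a lower macrophage share might account for changes called against untreated cells. Fewer macrophages would raise all T cell genes alike, yet 10 genes of the T lineage, such as Cd3e and Cd4, had a median log2 change of -0.11 ± 0.02 at 2 h and 0.0044 ± 0.043 at 8 h, where the smallest called rises were 0.49 and 0.28. In this paragraph ± is the SE over the genes of the set and leaves out the error of the 2 untreated arrays. Over arrays, the median SE of a single gene was 0.095 in both comparisons. The near absence of a rise in these T lineage genes argues against a change in cell shares alone as the source of the called rises. For the falls at 8 h, with a median of -0.54 over 420 genes, the markers decide less. The 5 markers bright in untreated cells had a median of -0.18 ± 0.12, but Lyz2 alone had -0.78, and 92 of the 420 falls went beyond it. Called falls are also selected for their size, which favours a larger median than that of the markers. Falls no larger than that of Lyz2 may still owe a part to fewer macrophages. With the marker mean as a covariate the median sizes stayed at 106% and 99.8% while the median SE grew from 0.10 to 0.13 and from 0.095 to 0.14, which decides little because the run term had already taken up most of the marker difference.

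Of the 420 genes that fell at 8 h against untreated cells, 310 were called higher in untreated cells than in baseline. The shared untreated arrays alone favour this overlap. All counts of overlap in this paragraph keep the baseline array in the run of its own number, where 1240 genes were called higher than in baseline. With that array placed with numbers 2 to 4, 116 genes in all were called higher, so 310 could not be reached. The overlap was not counted under that placing, where Il2 and Cd40lg were not called. With the untreated arrays used apart, 146 of 226 and 135 of 200 falls were called higher in the other untreated array than in baseline, where 11 and 9.79 would be if independent. One hypothesis is that these genes, among them Nr4a3, Il2 and Cd40lg, were raised by handling or fresh medium and fell with time in culture with or without IL-12, and another is that IL-12 lowered them between 2 h and 8 h. These may both hold, and they cannot be told apart with any value here, since no untreated culture of 8 h was analysed here.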
